A study of Mus musculus with 45 samples.

How the data were processed

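Pancreatic islets were measured by sequencing of polyadenylated RNA in 45 samples of mice from 3 inbred strains: C57BL/6J, CAST/EiJ, a wild-derived strain, and NZO/HlLtJ, a strain prone to obesity. Per the labels, females and males of each strain ate a control diet with 10% fat and fiber or a diet with 44% fat and fiber, described there as high in fat and sugar, from 6 weeks of age, and tissue was collected at 15 weeks. Libraries were made with a kit that selects polyadenylated RNA and were sequenced as paired reads of 150 bp, per the labels' protocols. Spike-in RNA was added before library construction, and its reads are not analysed here. Strain, sex and diet gave 12 groups of 3 or 4 samples. The labels give no replicate numbers, so replicates were numbered in accession order, and these numbers pair no samples. Each label names 1 strain, sex and diet, and none says outright which animal or how many animals a sample came from, so p-values measure the spread between these samples.

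The expected counts of reads per gene were deposited by the authors as a table of 22904 genes. Of its values, 80.6% lay within 1e-06 of a whole number, and totals differed between samples, as in a table not scaled for depth. The aligner, the counting tool and their settings are not given in the sources used here. The genome build was GRCm38 per the submitters' processing notes, which also name DESeq2. The log2 values of the second table were deposited by the authors as a variance-stabilised matrix over all 45 samples. Gene positions were deposited by the authors as coordinates in megabases, and 22763 of the genes were matched by identifier to the GENCODE M21 annotation of GRCm38, in which 22758 overlapped their deposited position. Whether counting used strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Of the genes selected by the naming rules that have an annotated transcript (147), 15 share at least 50% of their 31-base words with the transcripts of another gene and are called uncertain where they appear.

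Expected counts were rounded to whole numbers. Total counts per sample ran from 57203765 to 109950221, with a mean of 83542121, and no sample was left out. Averaged over genes, replicates differed by far more than counting error: the lowest chi-square per degree of freedom between 2 replicates of a group was 63.3, so no pair looked like a library deposited more than once. Genes were kept by the filterByExpr function of edgeR 4.0.16 with a minimum count of 10 on the groups of each fit, libraries were scaled by trimmed mean of M values, and genes were tested with the edgeR quasi-likelihood test in R 4.3.3. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all genes of a contrast. Diet effects within a strain, sex by diet interactions and sex differences were fitted on that strain's samples in 4 groups (16 of C57BL/6J, 15 of CAST/EiJ, 14 of NZO/HlLtJ). Strain by diet interactions and strain differences on the control diet were fitted on all 45 samples. A diet effect without a named sex is the mean of the female and male effects, and fold changes are high fat over control diet unless another pair is named. The sample identifiers in the labels fall into 3 runs of consecutive numbers, and the run, called the number range here, was a term of every fit, since consecutive numbers can mark samples handled together. In NZO/HlLtJ the ranges are spread unevenly over sex and diet, and the mean over sexes is less exposed to this than the effect in 1 sex. There the second range holds only control females and high-fat males, and the third only high-fat females and control males.

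Lists of 451 marker and pathway genes in 28 lists (443 genes in the table) were set up for islet cell types, other cell types that an islet preparation can hold, and pathways of secretion, stress, metabolism and cell division. Members were tested singly, both adjusted over all genes and adjusted over the list alone, and lists of at least 4 genes were tested in limma 3.58.1 with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move on balance in 1 direction. The stem families of the closing section use the same tests on symbols that share their letters, for stems with at least 10 tested genes. CPM values of named genes use library totals scaled by trimmed mean of M values factors over all 45 libraries. The acinar share of a library is the percent of its counts in the 23 genes of the acinar list. The acinar score is the mean log2 CPM of that list with a prior count of 0.5. Principal components were computed from the 1000 most variable genes of the authors' log2 matrix.

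Genes named in the text were chosen by fixed rules. For diet within a strain these are the 6 higher and 6 lower protein-coding genes with the largest fold among those past the threshold with a mean log2 CPM of at least 1 and the same sign in both sexes, the 2 members with the smallest p of each list with a called member, and always Ins1, Ins2, Gcg, Sst, Mafa, Slc2a2, Aldh1a3, Mki67 and Hspa5. For a strain by diet interaction these are 4 genes of each sign with the smallest p and up to 6 called list members. For a sex by diet interaction these are 3 genes of each sign with the smallest p. For a strain difference these are 4 genes of each sign with the largest fold and up to 8 list members with the smallest p. For a sex difference these are the sex-linked genes and 3 autosomal genes of each sign with the smallest p. Some genes these rules select are not reported here. Genes outside these rules are named as chosen after their values were seen.

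The groups, the fits and their terms, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were the DESeq2 1.42.0 Wald test, size factors by relative log expression, no filter on low counts, no range term, the acinar score as a covariate, all 45 samples in 1 fit, list tests with an estimated correlation, and leaving out each library in turn. Alternatives chosen after seeing the data were a fit without the 4 libraries with over 15% of counts in the acinar list, a fit within each number range alone, and the NZO/HlLtJ diet effect in the fit of all 45 samples with the acinar score. Size factors by relative log expression moved the median of all genes by at most 0.041 on the log2 scale in any contrast.

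The test was checked on simulated counts drawn from the real means, with 200 genes changed by 1.5-fold, 2-fold or 4-fold. It recovered 77.6%, 97% and 100% of these for diet in C57BL/6J (18318 simulated genes tested, 12 false calls among 195), 74.6%, 88.1% and 100% for diet in CAST/EiJ (18251 genes, 7 among 182), and 43.3%, 85.1% and 98.5% for diet in NZO/HlLtJ (18189 genes, 11 among 162). Recovery was 52.2%, 77.6% and 98.5% for the strain by diet interaction of NZO/HlLtJ against C57BL/6J (19897 genes, 6 among 158) and 70.1%, 88.1% and 98.5% for the difference between CAST/EiJ and C57BL/6J on the control diet (19919 genes, 10 among 181). The changed genes were picked above a floor of mean expression, and all genes were drawn independently without range or acinar effects. These rates therefore do not cover weakly expressed genes or variation that genes share. Splits of the libraries other than the real one were drawn with a fixed seed, up to 100 per comparison with the real one counted, and all splits were used where fewer exist.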

Results

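Gene expression was measured in pancreatic islets, the clusters of hormone-secreting cells of the pancreas, of 45 mouse samples in 12 groups. C57BL/6J had 4 samples in each of its groups of females and males on the control or the high-fat, high-sugar diet. CAST/EiJ had 4 in each except 3 in control males, and NZO/HlLtJ had 4 in each female group and 3 in each male group. Total counts per sample ran from 57203765 to 109950221. Insulin was among the most abundant transcripts in every group: Ins2, on chromosome 7 at 142678656 to 142699510 in GRCm38, made up 6.83% ± 1.48 (SD, n = 45) of counts, and the glucagon gene Gcg made up 2.40% ± 1.15. The sex-linked genes separated the labelled sexes. Xist, the X-inactivation transcript, averaged from 658.2 to 1290 CPM (counts relative to library totals scaled by trimmed mean of M values factors) in the 6 female groups and from 0.255 to 5.34 CPM in the male groups, where NZO/HlLtJ high-fat male 3 stood apart at 15.3 CPM. The Y-linked helicase Ddx3y averaged from 45.9 to 73.1 CPM in males and at most 0.00818 CPM in females.

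Digestive enzyme transcripts of acinar cells, the exocrine cells that surround islets, were present in every library in very different amounts. The 23 genes of the acinar list held between 0.064% and 40.6% of a library's counts. They held 14.5% ± 5.27 (SD, n = 3) in NZO/HlLtJ males on the high-fat diet against 5.17% ± 0.796 (n = 3) on the control diet. In the females of that strain they held 6.72% ± 2.39 against 3.98% ± 3.19 (n = 4 each). In C57BL/6J females the share was 5.81% ± 4.86 on the high-fat diet and 11.1% ± 9.34 on the control diet, and in CAST/EiJ females it was 3.37% ± 3.41 and 14.1% ± 17.8, the latter with 1 library at 40.6% and the others at most 7.32%. In males it was 6.03% ± 5.95 and 5.34% ± 3.05 in C57BL/6J, and 6.78% ± 9.02 (n = 4) and 2.21% ± 2.14 (n = 3) in CAST/EiJ. Strain accounted for 97.1% of the variance along the first principal component and 77% along the second, which held 53.3% and 22% of all variance, and the acinar score accounted for 59.1% along the third, which held 9.6%. Diet, taken over all strains at once, accounted for at most 2.4% of any of these 3. Within NZO/HlLtJ the second component parted the diets in each sex, given without a test. Females scored from -2.45 to 4.77 on the control and from 16.98 to 24.99 on the high-fat diet. Males scored from 10.92 to 28.9 and from 39.88 to 51.45. In C57BL/6J and CAST/EiJ the scores of the diets overlapped in each sex.

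**Figure D1:**
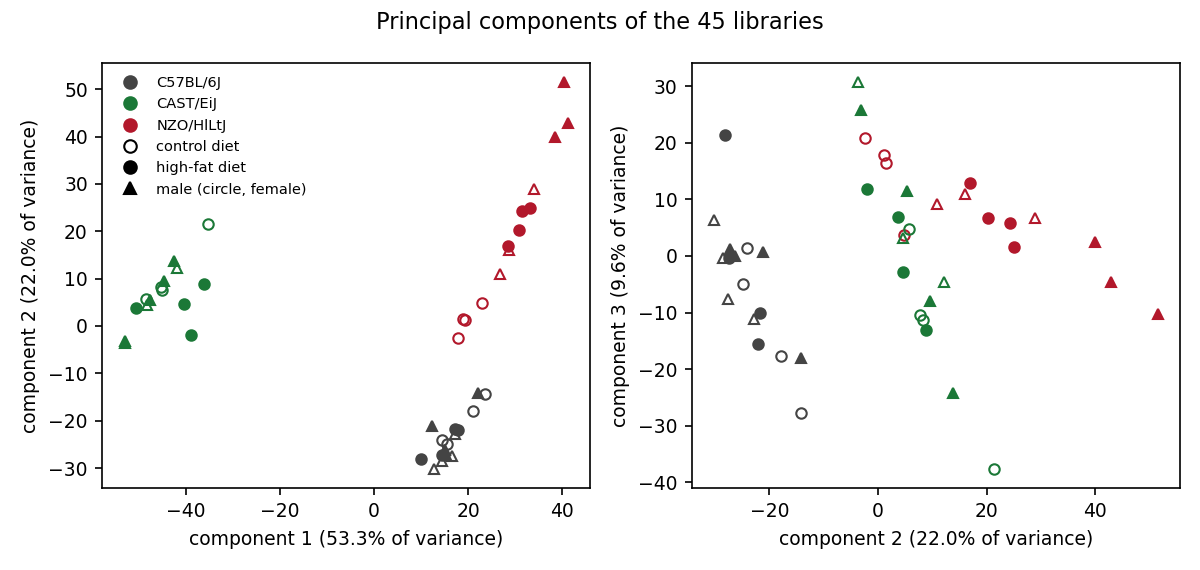
Scores of the 45 libraries on principal components 1 and 2 (left) and 2 and 3 (right), computed from the authors' log2 matrix; colours are strains, open symbols the control diet, filled symbols the high-fat diet, circles females and triangles males. The strains part along components 1 and 2, which hold 53.3% and 22% of the variance.

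**Figure D2:**
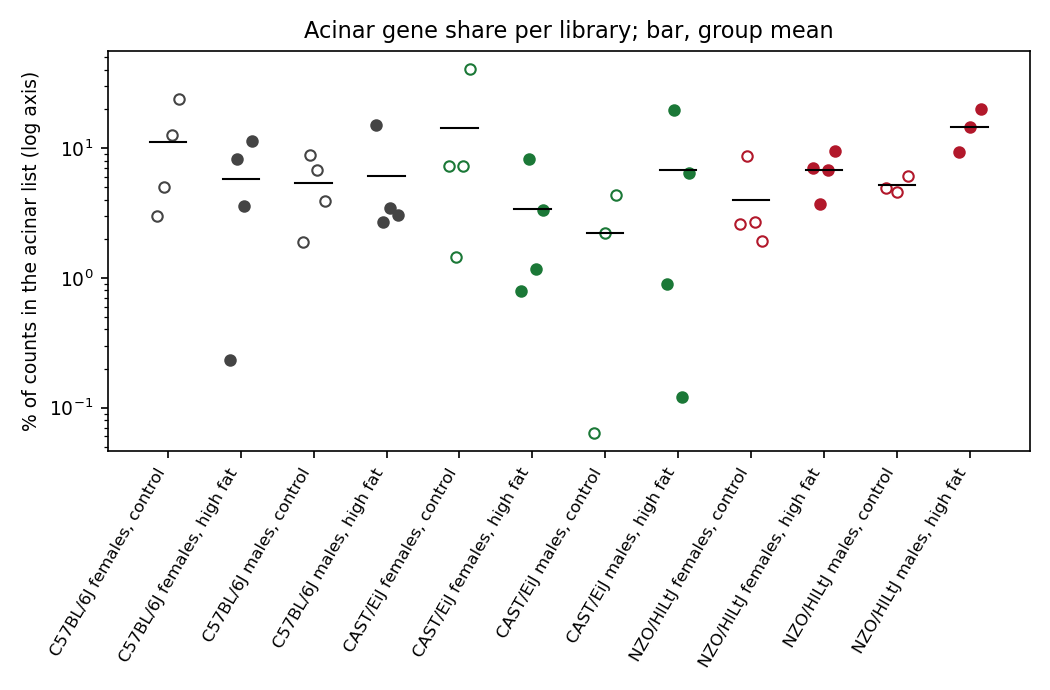
Percent of each library's counts in the 23 acinar genes, on a log axis, for the 12 groups; points are libraries, open for the control diet and filled for high fat, and bars are group means. Shares run from 0.064% to 40.6%, and the NZO/HlLtJ males on the high-fat diet average 14.5%.

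The series asked, per its title, how genotype and diet act together on susceptibility to type 2 diabetes, and the first comparison was the response of each strain to the high-fat diet. In C57BL/6J islets the genes that moved together were those of cell division. All members of the cell cycle list with a measured value (31) had a median log2 fold change of 0.58, and 23 of them rose when adjusted over the list alone, while 0 did over all genes. Mki67, a marker of dividing cells, had a log2 fold change of 0.89 ± 0.21 (SE, 16 samples, adjusted p = 0.371 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). It averaged 15.3 ± 5.41 CPM (SD, n = 4) in high-fat males against 6.04 ± 2.25 in control males, and 9.13 ± 1.97 against 6.67 ± 1.63 in females. The list passed the camera test (adjusted p = 6.59e-37 at the preset correlation) and had adjusted p = 0.0876 with an estimated correlation. By fry, which does not compare a list with the other genes, the list had adjusted p = 0.0414. Its mean log2 CPM was higher by 0.55 on the high-fat diet in a test chosen after the result was seen, which exchanged diets within each sex without the range term (two-sided exact permutation p = 0.00286; 0.01 with Benjamini-Hochberg adjustment over 21 score tests). In males alone 23 genes of the list rose when adjusted over the list alone, with a median of 0.88.

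Hormone and identity genes of C57BL/6J showed no called change: Ins1 and Ins2, the insulin genes, had log2 fold changes of -0.01 ± 0.15 and 0.06 ± 0.18, Gcg 0.09 ± 0.23, the somatostatin gene Sst 0.12 ± 0.15 and Slc2a2, the glucose transporter of beta cells, -0.03 ± 0.12. Mafa, a transcription factor of mature beta cells, stood at -0.32 ± 0.10, the aldehyde dehydrogenase gene Aldh1a3 at 0.26 ± 0.21 and the chaperone gene Hspa5 at -0.10 ± 0.16, with adjusted p of 0.536, 0.867 and 0.949. Camera also called the interferon response list (median 0.17) and the glucose-induced list (0.05) higher. It called lower the lists of the integrated stress response (-0.20), unfolded protein response (-0.10), oxidative phosphorylation (-0.04), stellate and fibroblast (-0.18), fatty acid synthesis (-0.07), fatty acid oxidation and PPAR targets (-0.05) and acinar (-0.24) genes. Each of these had adjusted p = 0.778 with an estimated correlation except the acinar list, with 0.807, whose mean fold change (0.04) differed in sign from its median and test. The Reg family list, which did not pass, had a median of 0.22 with a test direction of lower. Adjusted over the list alone, 2 glucose-induced genes and 1 of hormone granule and exocytosis rose, with 0 over all genes. By edgeR 0 of 18557 genes passed in C57BL/6J with both sexes, 0 in females and 0 in males. An unadjusted p under 0.05 was reached by 1340, 1021 and 1351 genes, and DESeq2 called 93, 37 and 144. The range term itself called 1820 genes in this strain. Without that term the 3 diet counts by edgeR stayed at 0, with 835, 674 and 909 genes at an unadjusted p under 0.05. Without high-fat male 3 the counts were 3 with both sexes and 2 in males, and 2 lists in place of 10 passed. Without high-fat male 1, 1 gene passed, and without control female 3 or control male 3, 5 or 6 lists did.

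In CAST/EiJ the high-fat diet moved no list member past the threshold over all genes, and no hormone gene passed the test. Ins1 and Ins2 had log2 fold changes of -0.12 ± 0.16 and -0.12 ± 0.18 (SE, 15 samples), Gcg -0.20 ± 0.16, Sst -0.28 ± 0.13, Mafa -0.28 ± 0.11 and Slc2a2 0.04 ± 0.11. Aldh1a3 stood at -0.00 ± 0.17, Mki67 at 0.10 ± 0.07 and Hspa5 at -0.14 ± 0.15, and the edgeR adjusted p of these genes lay between 0.711 and 0.999. The other islet endocrine list, markers of alpha, delta and other hormone cells, had a median of -0.20, with 2 of 14 members lower when adjusted over the list alone. Immediate early and handling genes, which respond within minutes to tissue disturbance, had a median of -0.68. Both lists passed camera, as did oxidative phosphorylation (-0.11), antioxidant and metallothionein (-0.05), interferon response (-0.18) and erythrocyte genes (-0.40), all lower, and Schwann cell markers (0.24), higher. The endocrine list had adjusted p = 0.7 with an estimated correlation and each of the others 0.79. By edgeR 0 of 18442 genes passed with both sexes, 0 in females and 0 in males. An unadjusted p under 0.05 was reached by 1275, 1621 and 408, and DESeq2 called 57, 144 and 22. In females alone 5 cell cycle genes rose when adjusted over the list alone (median 0.29). Without high-fat female 3 the counts were 7 with both sexes and 12 in females. In place of 7 lists, 11 passed without control male 1 and 4 without high-fat female 2.

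In NZO/HlLtJ many transcripts of the islet samples differed between the diets. Genes of beta cell identity fell, genes that beta cells normally keep silent rose, and transcripts of macrophages, lymphocytes, fibroblasts and dividing cells rose. Of 28 identity genes 17 fell and 0 rose over all genes (20 fell adjusted over the list alone; median log2 fold change -0.60, with -0.93 in males and -0.23 in females). Slc2a2 fell by 1.09 ± 0.23 on the log2 scale (SE, 14 samples, adjusted p = 0.0043), Trpm5, a cation channel involved in insulin secretion, by 1.29 ± 0.20, and Gipr, the receptor of the incretin hormone GIP, by 1.17 ± 0.20. The edgeR test called 6084 of 18517 genes, 3243 higher and 2841 lower, of which 1865 changed at least 2-fold.

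Insulin transcripts themselves did not pass the test: Ins1 stood at -0.18 ± 0.26 and Ins2 at -0.23 ± 0.27 on the log2 scale, respectively. Ins2 averaged 46160 ± 15720 CPM (SD, n = 3) in high-fat and 83520 ± 11160 in control males, but 84840 ± 12450 in high-fat and 65330 ± 8013 in control females (n = 4). Mafa stood at -0.75 ± 0.27, Gcg at 0.08 ± 0.22 and Sst at -0.34 ± 0.14, with adjusted p of 0.0515, 0.796 and 0.0681. Among other islet endocrine markers, 3 of 14 rose and 1 fell, the same counts as over the list alone; Hhex, a transcription factor of delta cells, rose by 0.64 ± 0.15. All 20 disallowed genes, those kept low in normal beta cells, rose (20 over the list alone; median 1.06), among them catalase, Cat (1.20 ± 0.17), and ornithine aminotransferase, Oat (0.80 ± 0.12). Of 12 dedifferentiation markers 7 rose and 1 fell (9 and 1 over the list alone). Examples were Cck, the gut hormone cholecystokinin, at 4.14 ± 0.72, the intermediate filament gene Vim at 1.22 ± 0.17 and Aldh1a3 at 0.78 ± 0.23. Of 19 hormone granule and exocytosis genes 5 fell and 1 rose, the same over the list alone. The vesicle release gene Rims2 fell by 0.58 ± 0.08. Camera called these lists except other islet endocrine. The identity list had adjusted p = 0.362 with an estimated correlation, the disallowed list 0.267, dedifferentiation 0.104 and exocytosis 0.649. By fry, which does not compare a list with the other genes, they had adjusted p of 0.0073, 0.00348, 5.68e-05 and 0.146 in that order. In this contrast 43.8% of all genes had an unadjusted p under 0.05. The mean log2 CPM of the identity list changed by -0.615 (exact permutation p = 0.0114, and 0.0299 adjusted over the 21 score tests).

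**Figure D3:**
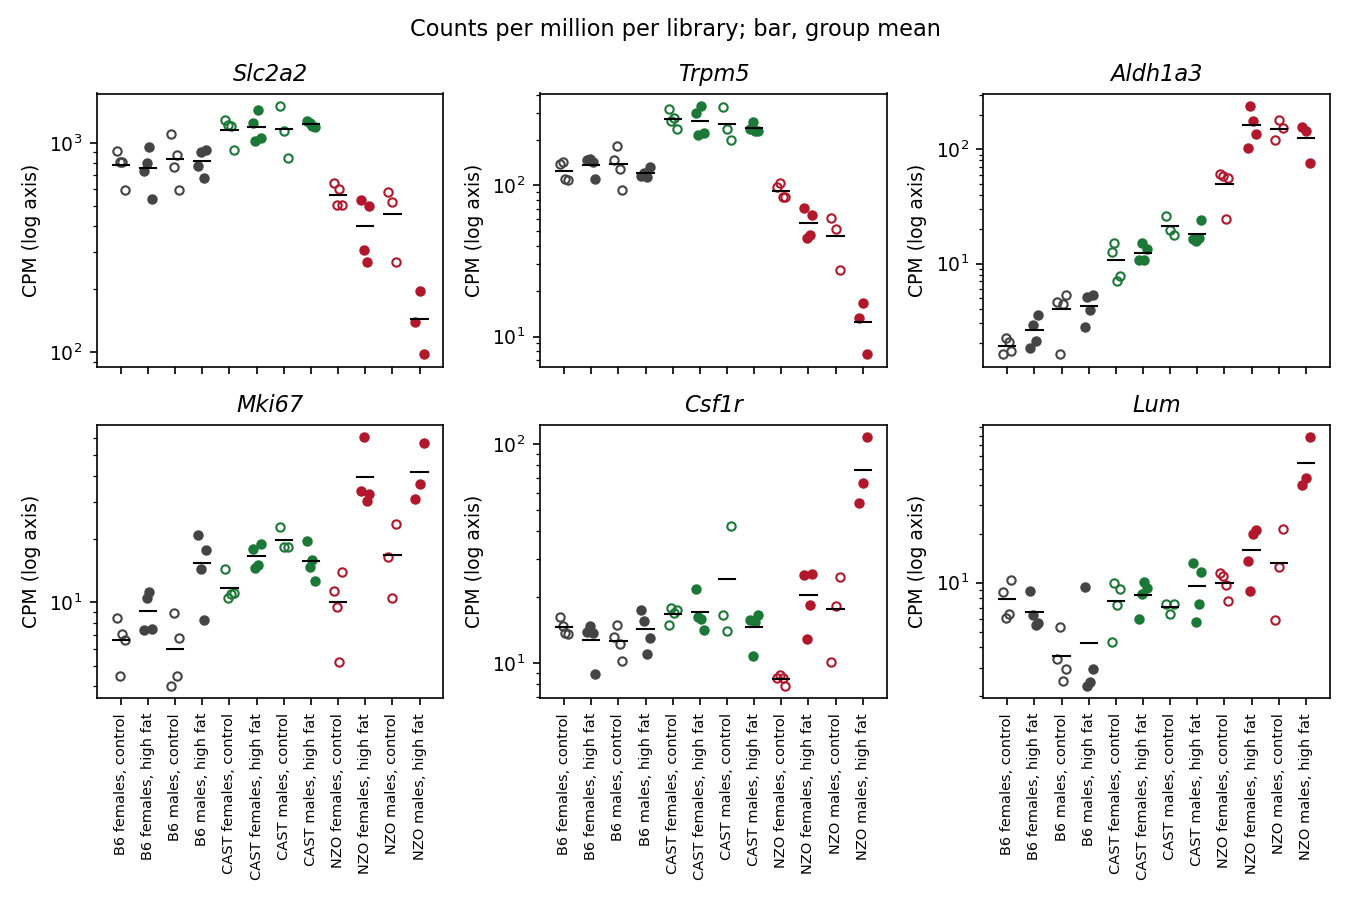
CPM per library, on log axes, for 6 genes in the 12 groups; points are libraries, open for the control diet and filled for high fat, and bars are group means. In NZO/HlLtJ males Slc2a2 averages 457.7 CPM on the control diet and 143.9 on the high-fat diet, and Csf1r 17.6 and 76.1.

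Markers of immune and connective tissue cells rose in the same samples. All 17 macrophage markers rose (17 over the list alone; median 1.89), including Csf1r, the receptor that macrophages need to survive, at 1.74 ± 0.21, and the Fc receptor gene Fcgr3 at 1.96 ± 0.24. Of 13 lymphocyte markers 11 rose (12 over the list alone; median 2.00), with the B cell receptor gene Cd79b at 2.80 ± 0.44 and Cd52 at 1.96 ± 0.36. All 16 stellate and fibroblast genes rose (16 over the list alone; median 1.41), such as the matrix proteoglycan gene Lum (1.48 ± 0.21) and Pdgfrb (0.76 ± 0.11). Of 22 interferon response genes 19 rose (21 over the list alone; median 1.29), with Zbp1, a nucleic acid sensor, at 2.57 ± 0.40 and Oas1a, uncertain because of near-identical copies, at 1.39 ± 0.23. Duct markers rose in 6 of 10 cases (7 over the list alone), with osteopontin, Spp1, at 2.03 ± 0.28 and Anxa2 at 1.01 ± 0.15. Endothelial markers moved less: 8 of 12 rose and 1 fell (8 and 1 over the list alone; median 0.32), with Cd34 at 0.58 ± 0.10 and Pecam1 at 0.47 ± 0.10. Schwann cell markers rose in 5 of 7 cases (6 over the list alone), with Ngfr at 1.04 ± 0.21 and Cdh19 at 0.69 ± 0.17, and Fabp4, a lipid carrier of fat cells and macrophages, rose by 1.10 ± 0.23. Camera called these lists, and with an estimated correlation the macrophage and stellate lists had adjusted p = 0.222, duct 0.267, lymphocyte, interferon and Schwann 0.37, and endothelial 0.61. By fry macrophage and stellate had adjusted p = 0.00142, duct 0.00348, lymphocyte and interferon 0.0145 and endothelial 0.0318. Erythrocyte, immediate early and sex-linked genes had 0 called members of 5, 11 and 3, and 0 over each list alone.

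Acinar transcripts rose too, so these groups moved together with the exocrine share given above. Of 23 acinar genes 20 rose (22 over the list alone, median 1.29). The list had adjusted p = 0.37 with an estimated correlation and 0.0145 by fry. The trypsinogen genes Try5 (2.73 ± 0.44) and Prss1 (8.13 ± 1.12) had the smallest p of the list, and both share most of their sequence with other genes and are uncertain. Reg3g and Reg1, secreted proteins of the injured exocrine pancreas, rose by 2.84 ± 0.85 and 1.01 ± 0.36 (2 of 6 Reg genes, also over the list alone, and the list did not pass). Reg1 lost its call without the range term (0.88 ± 0.34, edgeR adjusted p = 0.0593). With the acinar score as a covariate within this strain 0 genes were called by edgeR (3115 at an unadjusted p under 0.05; DESeq2 without it called 6709). The median log2 fold change of the genes called without it, other than acinar genes, was 0.46 in the direction of their call with a median SE of 0.25, against 0.61 and 0.14 before, and 97.5% had the same sign. List medians moved unevenly: duct from 0.96 to 0.165, disallowed from 1.06 to 0.43 and endothelial from 0.32 to 0.10. Dedifferentiation went from 1.00 to 0.54, lymphocyte from 2.00 to 1.135 and identity from -0.60 to -0.40. Macrophage went from 1.89 to 1.44, stellate and fibroblast from 1.41 to 0.92 and cell cycle from 1.42 to 1.23. Also in that fit within the strain, Reg1 changed sign to -0.66 ± 0.17 and Reg3g to -0.025 ± 0.698, with adjusted p of 0.217 and 0.989. In the fit of all 45 samples 3 acinar genes were called without the score, with a list median of 0.98. With the score added there 6496 genes were called, 14 of them acinar with a list median of -0.44.

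Cell division and parts of metabolism also changed in NZO/HlLtJ. Of 31 cell cycle genes 29 rose (30 over the list alone; median 1.42), with Mki67 at 1.57 ± 0.26, the replication helicase gene Mcm3 at 1.12 ± 0.14 and the spindle motor gene Kif11 at 1.44 ± 0.19. Mki67 averaged 39.4 ± 14.3 CPM (SD, n = 4) in high-fat and 10.0 ± 3.71 in control females. Glucose-induced genes rose in 4 of 9 cases and fell in 1, also over the list alone, with Arrdc4 at 1.43 ± 0.23. Of 21 genes of fatty acid oxidation and PPAR targets 7 rose and 2 fell (8 and 3 over the list alone), with the fatty acid transporter gene Cd36 at 1.62 ± 0.32 and Ucp2 at 0.47 ± 0.09. Of 20 integrated stress response genes 4 fell and 1 rose, also over the list alone; the amino acid transporter gene Slc7a5 fell by 0.52 ± 0.08 and Sesn2 by 0.59 ± 0.10. Camera called these 4 lists, and with an estimated correlation cell cycle had adjusted p = 0.267, glucose-induced 0.37, fatty acid oxidation 0.648 and stress response 0.649. By fry they had adjusted p of 0.00142, 0.0145, 0.0686 and 0.172 in that order.

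Other lists split or stayed below the list test. In fatty acid synthesis 3 of 17 genes rose and 4 fell, also over the list alone, with the desaturase gene Fads2 at 0.74 ± 0.09 and the elongase gene Elovl5 at -0.46 ± 0.09. In cholesterol synthesis 2 of 24 fell and 0 did over the list alone, and the list's median (0.02) and test direction (lower) differed in sign. Glycolysis had 1 of 12 higher and 2 lower, also over the list alone, with enolase, Eno1, uncertain because of a near-identical copy, at 0.62 ± 0.14 and Aldoa at -0.32 ± 0.07. In oxidative phosphorylation 1 of 34 rose and 2 fell, also over the list alone; Sdha fell by 0.41 ± 0.07 and Ndufs1 by 0.30 ± 0.07. Antioxidant and metallothionein genes had 2 of 16 higher and 4 lower (2 and 5 over the list alone); Nqo1, a quinone reductase, fell by 1.48 ± 0.23 and the peroxiredoxin gene Prdx1 rose by 0.30 ± 0.09. In the unfolded protein response 1 of 19 rose and 0 did over the list alone: Creld2, by 0.69 ± 0.25, while Hspa5 stood at 0.23 ± 0.21.

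Among protein-coding genes past the threshold with a mean log2 CPM of at least 1 and the same sign in both sexes, the highest besides Prss1 were Prss3, another uncertain trypsinogen (5.67 ± 0.68), the membrane protein gene Tm4sf20 (4.42 ± 0.90), the casein gene Csn3 (4.32 ± 0.80), the sugar transporter gene Slc5a10 (4.17 ± 1.13) and Cck. The lowest were Mcoln3, a lysosomal cation channel, which fell by 3.08 ± 0.62, T2 by 2.82 ± 0.51, the cytochrome P450 gene Cyp4f39 by 2.61 ± 0.47, Grid2ip by 2.34 ± 0.33, Otoa by 2.31 ± 0.38 and the potassium channel gene Kcnj12 by 2.25 ± 0.35. Adjusted p of these 12 genes lay between 0.00112 and 0.0152. Of the 6084 called genes, 5475 (90%) had the same sign in females and males, given without a test; calls on the mean of both sexes favour such genes, and over all genes, which are not independent replicates, the female and male fold changes had a Pearson correlation of 0.217 (Spearman 0.238). The count was 3329 without control male 1 and 0 among the samples of the first number range alone, with 4708 there at an unadjusted p under 0.05.

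**Figure D4:**
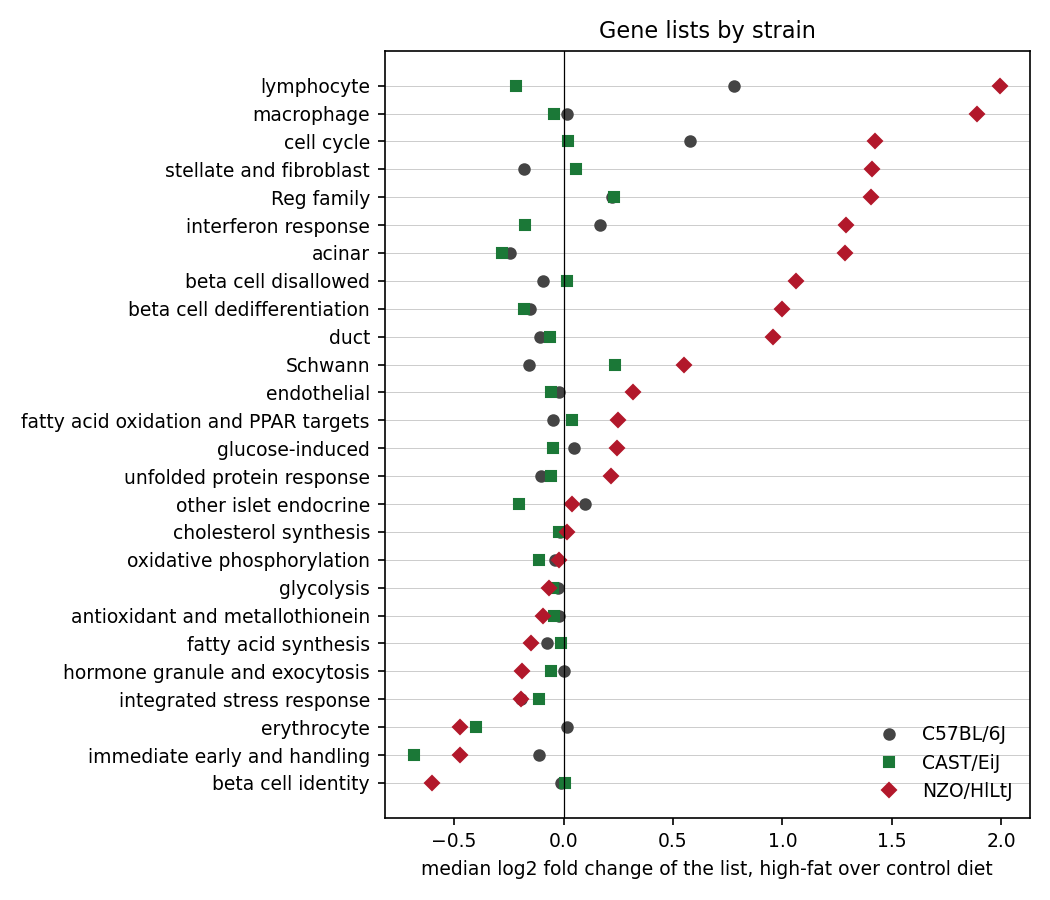
Median log2 fold change of each gene list of at least 4 genes, high-fat over control diet, for C57BL/6J (circles), CAST/EiJ (squares) and NZO/HlLtJ (diamonds), lists ordered by NZO/HlLtJ. Lymphocyte and macrophage markers stand at 2.00 and 1.89 in NZO/HlLtJ and beta cell identity at -0.60.

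Within NZO/HlLtJ, males carried more called genes than females. In males all 20 disallowed genes rose (20 over the list alone; median 1.93), 14 of 28 identity genes fell (23 over the list alone; median -0.93), and 16 of 17 macrophage and 13 of 16 stellate and fibroblast genes rose (17 and 16 over the lists alone; medians 2.37 and 2.45). In females 0 list members passed over all genes, while over the list alone 30 of 31 cell cycle genes (median 1.59), 16 of 17 macrophage genes (1.5) and 8 of 13 lymphocyte genes (2.47) rose, and 8 of 14 other islet endocrine genes fell (-0.70). Of the identity genes 0 passed by edgeR in females over the list alone (median -0.23), and 0 had a diet effect that differed between the sexes, over all genes or over the list alone (median male minus female difference -1.07). The edgeR test called 2520 genes in males (1620 higher, 900 lower) and 3 in females, all lower and named after their values were seen. Slc5a7, the choline transporter of nerve terminals, fell by 3.30 ± 0.38, Cplx1, complexin of vesicle release, by 2.84 ± 0.34, and the monoamine transporter gene Slc29a4 by 1.17 ± 0.15. An unadjusted p under 0.05 was reached by 5745 and 2861 genes, and DESeq2 called 3954 and 786. These counts rest on few libraries and on the range term. Without control male 1 the male count was 0, without control male 2 it was 1366 and without control male 3 it was 3837. The female count was 55 without high-fat female 1, 1 without control female 3, and 0 without control female 1 or 4 or high-fat female 2 or 3. Without the range term the counts were 4759 in males and 1314 in females, with 1 of the 3 named female genes among them, and with all 45 samples in 1 fit 6866 and 2970. With the acinar score as a covariate within the strain they were 0 in males and 5 in females (2081 and 2660 at an unadjusted p under 0.05), and with the score in the fit of all 45 samples 5937 and 2857.

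**Figure D5:**
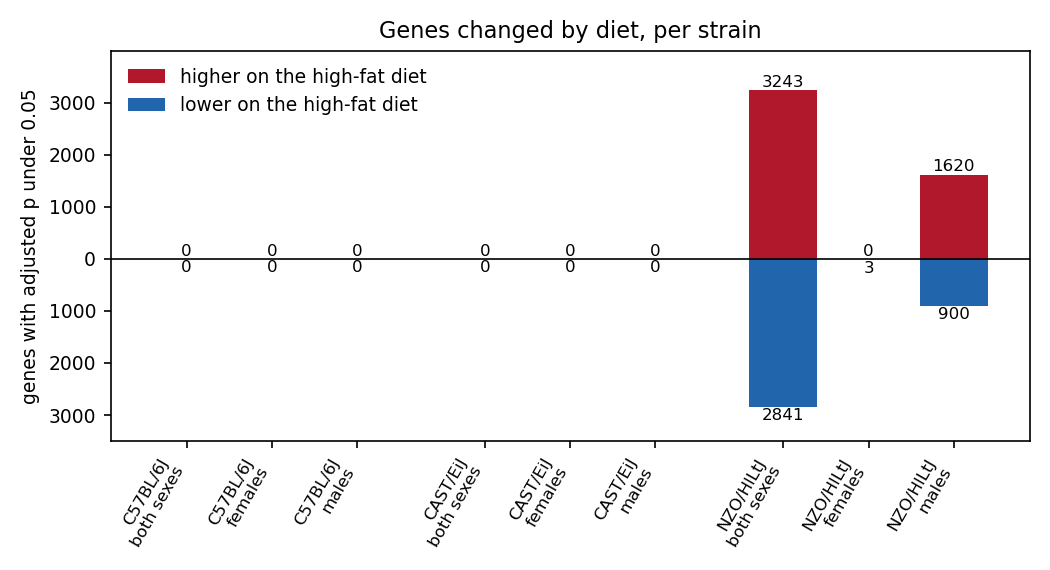
Number of genes with an adjusted p under 0.05 (edgeR) that are higher (red, upward) or lower (blue, downward) on the high-fat diet, for each strain with both sexes, females and males. C57BL/6J and CAST/EiJ have 0 throughout; NZO/HlLtJ has 3243 higher and 2841 lower with both sexes.

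The test of the difference between the sexes named a pair of neuronal genes in NZO/HlLtJ. Slc5a7 and Cplx1 had a male minus female difference of the log2 diet effect of 6.35 ± 0.76 and 5.43 ± 0.65 (SE, 14 samples, edgeR adjusted p = 0.0199 each). Without adjustment for the number range the group means differ less: Slc5a7 averaged 2.73 ± 0.841 CPM in control and 1.08 ± 0.923 in high-fat females (SD, n = 4), and 1.23 ± 0.955 and 1.76 ± 0.293 in males (n = 3). The next genes did not pass: Dkk3 at 3.71 ± 0.55, Srl at -2.52 ± 0.45, Cox6a2, a muscle-type oxidase subunit, at -2.06 ± 0.40 and Gcdh at -1.24 ± 0.25, with adjusted p from 0.091 to 0.118. Over the list alone, 15 of 20 disallowed, 12 of 16 stellate and fibroblast and 8 of 14 other islet endocrine genes had a more positive diet effect in males, with 0 over all genes. In all 2 genes passed (2198 at an unadjusted p under 0.05; 504 by DESeq2). Without the range term the count was 52 and neither gene was called: Slc5a7 stood at 1.84 ± 1.03 and Cplx1 at 1.52 ± 0.93, with adjusted p of 0.321 and 0.367. Srl and Gcdh passed in that fit (edgeR adjusted p = 0.0431 each). The count was 2852 with all 45 samples in 1 fit and 14 without the libraries over 15% acinar. Leaving out 1 library gave 58 without high-fat female 1, 17 without control male 3, 14 without high-fat male 3, 1 without control female 3 or high-fat female 3, and 0 without control female 1 or 4, high-fat female 2 or 4, control male 1 or 2, or high-fat male 1 or 2.

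In C57BL/6J and CAST/EiJ no gene differed in its diet response between the sexes. The C57BL/6J genes of each sign with the smallest p were Zbed6 (1.38 ± 0.24, male minus female), which is uncertain because its sequence lies within another gene's, Vtcn1, an inhibitor of T cells (3.67 ± 0.67), Plbd1 (1.33 ± 0.25), Dpysl2 (-0.33 ± 0.07), Zfp428 (-0.72 ± 0.17) and the glycolytic gene Gapdh (-0.44 ± 0.11), each with adjusted p = 0.505. Over the list alone 7 of 17 macrophage genes (median 0.41) and 4 of 5 erythrocyte genes were more positive in males. In CAST/EiJ these were Sgms1 (0.38 ± 0.10), Gfra1 (0.53 ± 0.13), Ceacam2, uncertain because of a near-identical copy (1.15 ± 0.29), Mki67 (-0.81 ± 0.15), the topoisomerase gene Top2a (-0.98 ± 0.20) and Ikzf4 (-0.94 ± 0.19), each with adjusted p = 1. Over the list alone 8 of 31 cell cycle genes were more negative in males and 22 of 23 acinar genes more positive. By edgeR 0 of 18557 and 0 of 18442 genes passed, with 1100 and 759 at an unadjusted p under 0.05 and 101 and 31 by DESeq2. Without control female 3 of C57BL/6J the count was 1, and without high-fat female 3 of CAST/EiJ it was 7.

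The comparison of diet responses between strains set NZO/HlLtJ apart from both others. Against C57BL/6J, all 17 macrophage genes had a more positive response in NZO/HlLtJ (17 over the list alone; median difference 1.85), among them C1qc at 1.92 ± 0.26 and C1qb at 1.85 ± 0.26, subunits of complement C1q. Others were the surface marker gene Adgre1 at 2.06 ± 0.28, Fcgr3 at 1.94 ± 0.27 and the lysosomal gene Cd68 at 1.84 ± 0.28 (SE, 45 samples in the fit, edgeR adjusted p from 1.67e-05 to 6.79e-05). The matrix gene Emilin2 (2.64 ± 0.34) and the scavenger receptor gene Scarf2 (1.46 ± 0.19) were also more positive. Negative differences with the smallest p were those of Cib3 (-3.39 ± 0.36), the neuronal enolase gene Eno2 (-0.76 ± 0.09), Gad1, the enzyme that makes GABA (-1.84 ± 0.23), Tmem25 (-1.15 ± 0.15) and Trpm5 (-1.29 ± 0.20). Identity genes were more negative in 16 of 28 cases (19 over the list alone; median -0.54), and disallowed genes more positive in 19 of 20 (19; 1.10). Stellate and fibroblast genes were more positive in 15 of 16 cases (16 over the list alone), cell cycle in 16 of 31 (23) and interferon response in 15 of 22 (18, with 1 lower over the list alone).

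The edgeR test called 4128 of 20306 genes in this comparison, 1959 more positive and 2169 more negative, and DESeq2 called 4737. The leading sign depended on the method: 2169 were more positive and 1832 more negative with relative log expression factors, and 2566 and 2171 by DESeq2. Camera called 14 lists, of which macrophage and dedifferentiation had adjusted p = 0.0229 with an estimated correlation. Those whose call was lost were identity, disallowed and stellate (adjusted p = 0.117 with an estimated correlation), interferon and duct (0.187), cell cycle (0.209), fatty acid oxidation (0.471), glucose-induced (0.563), endothelial (0.622), exocytosis (0.66), and acinar and lymphocyte (0.734).

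Against CAST/EiJ all 17 macrophage genes had a more positive response in NZO/HlLtJ (17 over the list alone; median 2.05), with Csf1r at 2.04 ± 0.28, Cd68 at 2.09 ± 0.29, C1qc at 1.97 ± 0.26, C1qb at 1.93 ± 0.26, C1qa at 1.56 ± 0.21 and the adaptor gene Tyrobp at 2.05 ± 0.29. Pfkfb3, a regulator of glycolysis, stood at 1.64 ± 0.21 and the sensor gene Tlr13 at 2.24 ± 0.30. Negative differences with the smallest p were those of Cib3 (-3.23 ± 0.37), the sialyltransferase gene St8sia1 (-1.77 ± 0.20), Jph3 (-1.51 ± 0.18) and Mreg (-2.21 ± 0.27), with edgeR adjusted p from 2.07e-06 to 1.74e-05 over all these genes. Cell cycle genes were more positive in 29 of 31 cases (29 over the list alone), identity genes more negative in 17 of 28 (18), and disallowed genes more positive in 18 of 20 (19). In all 5363 of 20306 genes passed, 2566 more positive and 2797 more negative (5825 by DESeq2). With relative log expression factors 2906 were more positive and 2298 more negative, and by DESeq2 3228 and 2597, so the leading sign depended on the method. Of 12 lists called by camera, macrophage had adjusted p = 0.0246 with an estimated correlation and dedifferentiation 0.0185. The calls lost were cell cycle (adjusted p = 0.0582 with an estimated correlation), interferon (0.129), identity (0.148), disallowed and stellate (0.202), duct and glucose-induced (0.307), lymphocyte and endothelial (0.594) and acinar (0.904).

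CAST/EiJ and C57BL/6J differed in diet response at 3 genes, all more positive in CAST/EiJ: 2210418O10Rik (4.15 ± 0.68, adjusted p = 0.0129), 9930111J21Rik2, uncertain because of near-identical copies (5.74 ± 1.00, adjusted p = 0.0214), and Gm12174 (2.14 ± 0.40, adjusted p = 0.0362), the last named after its values were seen. The cell cycle list had a median difference of -0.56 with 7 of 31 genes lower over the list alone and 0 over all genes. Camera called this list at the preset correlation only, with adjusted p = 0.198 at an estimated correlation. It also called other islet endocrine (median -0.31; adjusted p = 0.654 with an estimated correlation) and, each with 0.723, interferon (-0.34), oxidative phosphorylation (-0.08), lymphocyte (-1.94), immediate early (-0.79), Schwann (0.46), stellate (0.20), fatty acid oxidation (0.08) and glucose-induced genes (-0.16). Of 20306 genes 645 had an unadjusted p under 0.05, and DESeq2 called 22. The count was 21 without CAST/EiJ high-fat female 3, 1 without its control female 1, 2, 3 or 4 or high-fat male 1, and 0 without its control male 1, 2 or 3. Without C57BL/6J control female 4, 6 lists passed in place of 10. Across genes, which are not independent replicates, the diet fold changes of NZO/HlLtJ had a Pearson correlation of 0.079 with those of C57BL/6J and -0.06 with those of CAST/EiJ, and those of CAST/EiJ and C57BL/6J one of 0.131 (Spearman -0.056, -0.146 and 0.222).

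In control-diet islets of NZO/HlLtJ against C57BL/6J, Aldh1a3 was higher by 4.96 ± 0.26 on the log2 scale (SE, 45 samples in the fit), at 49.8 ± 17.0 CPM (SD, n = 4) in control females against 1.91 ± 0.287 in those of C57BL/6J. The secretory granule genes Vgf (3.47 ± 0.19) and Scg5 (1.5 ± 0.11), the antiviral gene Mx1 (7.01 ± 0.40), the pericyte gene Rgs5 (1.58 ± 0.10) and Gapdh (1.20 ± 0.10) were higher too. Endothelial genes were higher in all 12 cases (12 over the list alone), oxidative phosphorylation genes in 27 of 34 (28), cell cycle genes in 24 of 31 (25) and unfolded protein response genes in 14 of 19 (14), while 9 of 14 other islet endocrine genes were lower (10). Among protein-coding genes with a mean log2 CPM of at least 1 the largest folds reported here were those of Hist2h2aa2 (9.95 ± 0.60) and Hba-a1 (8.11 ± 0.46), both uncertain because of near-identical copies, Tpm3-rs7 (9.59 ± 0.34), Zfp607 (-10.03 ± 0.50), the interferon-inducible gene Mndal (-9.77 ± 0.59), the histocompatibility gene H2-Q2 (-9.62 ± 0.27) and Lefty1 (-8.22 ± 0.57). In all 8729 of 20306 genes (43%) passed, 4608 higher and 4121 lower, with adjusted p of the named genes at or below 5.18e-12 by edgeR. No list was tested against the other genes in this comparison.

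In CAST/EiJ against C57BL/6J, interferon response genes were lower in 12 of 22 cases and higher in 4 (13 and 4 over the list alone; median -0.86). The RNA sensor gene Ifih1 stood at -2.36 ± 0.13, Oas1a, which is uncertain, at -2.86 ± 0.22 and Ifi44 at -4.42 ± 0.36. Usp18, a negative regulator of interferon signalling, was higher by 1.57 ± 0.12. Of 17 fatty acid synthesis genes 7 were higher and 1 lower, also over the list alone, with Fads2 at 1.28 ± 0.11, Elovl6 at 0.94 ± 0.07 and Fads1 at 0.91 ± 0.07. Fabp3, a fatty acid carrier of the dedifferentiation list, was higher by 1.98 ± 0.14. Cell cycle genes were higher in 25 of 31 cases and lower in 2, and integrated stress response genes lower in 10 of 20, the same over the lists alone. By the same rule the largest folds reported here were those of AK157302 (13.08 ± 0.47), the elastase gene Cela3a (11.43 ± 1.48), Fam213b (-12.44 ± 0.64) and, each uncertain because of near-identical copies, Eno1b (9.83 ± 0.40), the amylase genes Amy2a3 (-12.59 ± 1.58) and Amy2a4 (-10.61 ± 1.44) and Tgtp2 (-11.58 ± 1.01). In all 9841 of 20306 genes passed, 4996 higher and 4845 lower (edgeR; adjusted p of the named genes at most 1.17e-07).

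Between control males and females the called genes included X-linked and Y-linked genes in each strain and, in C57BL/6J and CAST/EiJ, a complement gene. C7, of the terminal complement pathway, was higher in males by 3.74 ± 0.35 on the log2 scale in C57BL/6J and 5.02 ± 0.59 in CAST/EiJ, at 9.90 ± 1.36 CPM (SD, n = 4) in C57BL/6J males and 0.723 ± 0.278 in females. Xist, Ddx3y and Kdm5d passed in C57BL/6J and CAST/EiJ. In NZO/HlLtJ Ddx3y and Kdm5d passed and Xist, at 887 ± 132.6 CPM in females (n = 4) and 0.362 ± 0.492 in males (n = 3), had adjusted p = 0.0711. Xist passed there without the range term (edgeR adjusted p = 0.014). In C57BL/6J Enpp2, which makes lysophosphatidic acid (-1.36 ± 0.17), the calcium channel gene Cacna1i (-1.33 ± 0.20) and the oxidase gene Nox4 (-1.42 ± 0.21) were lower in males. The call of Nox4 was lost without the range term (-1.38 ± 0.30, edgeR adjusted p = 0.144). Lrrc1 (0.30 ± 0.05) and Gpr45 (0.48 ± 0.09) had adjusted p of 0.0512 and 0.0574. In CAST/EiJ the apolipoprotein gene Apob (1.54 ± 0.23) and Mki67 (0.73 ± 0.11) were higher and the chemokine gene Cx3cl1 (-0.64 ± 0.10) and the phosphatase gene Ptprd (-0.45 ± 0.07) lower in males. The calls of Mki67, Cx3cl1 and Ptprd were lost without the range term (edgeR adjusted p of 0.145, 0.302 and 0.113). The clock gene Dbp (-2.06 ± 0.34) had adjusted p = 0.055 by edgeR, and 0.0219 without the range term. In NZO/HlLtJ Cplx1 (-3.25 ± 0.40) and Slc5a7 (-3.69 ± 0.46) were lower in males, calls lost without the range term (-1.05 ± 0.67 and -1.12 ± 0.74, adjusted p of 0.43 and 0.445). Kdm6a, an X-linked histone demethylase named after its values were seen, was also lower (-1.02 ± 0.13). Serpina3i (8.82 ± 1.5), Mcoln2 (3.51 ± 0.71), Derl3 (1.84 ± 0.38) and Slc29a4 (-1.10 ± 0.17) had adjusted p from 0.0711 to 0.212. Mcoln2, Derl3 and Slc29a4 passed without the range term (edgeR adjusted p of 0.0237, 0.018 and 0.00843). Over the lists alone 12 of 16 stellate and fibroblast genes were lower in C57BL/6J males, and 22 of 23 acinar genes lower and 13 of 31 cell cycle genes higher in CAST/EiJ males, with at most 1 of any such list over all genes.

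The edgeR test called 16 genes in C57BL/6J (3 higher and 13 lower in males), 11 in CAST/EiJ (6 and 5) and 5 in NZO/HlLtJ (2 and 3), and DESeq2 called 338, 226 and 197. The C57BL/6J count was 181 without control male 2, 26 without control female 1, 10 without control female 3, 9 without control male 3, 8 without control male 4 and 7 without control male 1 or control female 4. The CAST/EiJ count was 7 without control female 1, 6 without control female 3 or 4 and 5 without control male 2. The NZO/HlLtJ count was 3 without control female 1, 2 without control male 2 and 1 without control male 1, and 48 without the range term.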

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

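Of the tests in this part, those of acinar carry-over, of the beta cell share, of a single library, of the number range and of the control male in the first range were chosen only after the result was seen. The diet response of NZO/HlLtJ islets came with more acinar RNA, so acinar tissue carried over with the islets is a candidate explanation. Ctrb1, an abundant digestive enzyme gene chosen after its values were seen, averaged 26030 ± 12200 CPM in high-fat and 7593 ± 2335 in control males (SD, n = 3). The Amy2 amylase genes together held 4.76% ± 1.03 of counts in these high-fat males and 3.25% ± 0.244 in the control males. Acinar transcripts thus did not all differ by the same factor, and why was not tested. With the acinar score as a covariate within the strain, the median log2 fold change of the called genes other than acinar ones in the direction of their call was 0.46 with a median SE of 0.25, against 0.61 and 0.14 without it, and 0 were called by edgeR (3115 at an unadjusted p under 0.05). The groups and ranges left 21.9% of the variance of the score to that fit. Whether this or acinar content ended the calls was not tested. With the slope of the score taken from all 45 samples, 6496 genes were called, 5325 of them among the 6084. The acinar list had a median of -0.44 in that fit, with 14 genes called. The score varied more within the groups of CAST/EiJ (residual SD 2.376) and C57BL/6J (1.411) than of NZO/HlLtJ (0.684). The slope therefore came mostly from the other strains. These calls argue against carry-over as the whole cause only if the slope is alike in all strains, which was not tested. The lowest count with 1 library left out, 3329 without control male 1, argues against a single library. A lower share of beta cells alone would raise the markers of all other cell types alike. The macrophage score rose by 1.90 and the endothelial score by 0.23 on the log2 scale, a difference of 1.66. Its two-sided exact permutation p, without the range term, was 0.00143, the smallest it can give, and 0.00601 with Benjamini-Hochberg adjustment over 21 score tests. This argues against a lower share as the only cause, but not against it as a part, also of the shifts in identity and disallowed genes. Such a lower share, carry-over as a part, a response of islets to the diet, more macrophages around or in them, and differences in isolation that follow the diet stay open.

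The count of called genes was higher in NZO/HlLtJ males (2520) than in females (3), while the test of the difference between the sexes called 2 genes. The number range differs between diets in both sexes, and without its term the counts were 4759 in males and 1314 in females, in the same order. That fit leaves any effect of the range in the counts, so it cannot decide whether the range makes the order. With the term estimated over all 45 samples the counts were 6866 in males and 2970 in females, which takes the range to act alike in all strains. Tested itself, the range term called 1820 genes in C57BL/6J, 32 in CAST/EiJ, 0 in NZO/HlLtJ and 1220 over all 45 samples. These counts were not compared by a test, and a count of 0 does not show that the range had no effect. The range as a part of that order stays open. The acinar share averaged 14.5% in high-fat and 5.17% in control males, and with the acinar score as a covariate within the strain 0 genes were called by edgeR in males and 5 in females, against 5937 and 2857 with the score in the fit of all 45 samples, so a part of acinar tissue in that order stays open. The 1 control male in the first range carries much of the male count: without it 0 genes were called by edgeR with the range term and 2282 without that term. Once it is left out, no range holds males of both diets. The male diet effect with the term then rests on range differences estimated in the females. The loss of calls therefore cannot tell an effect of this library from that layout. A difference between the sexes in the response stays open, and leaving out 1 library moved the male count to 1366 without control male 2 and 3837 without control male 3, and the female count to 55 without high-fat female 1, 1 without control female 3 and 0 without control female 1 or 4 or high-fat female 2 or 3.

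Of 100 splits of the libraries, only the real 1 called as many as 6084 genes for diet in NZO/HlLtJ. This is the smallest share these splits can give, so chance alone is unlikely. The highest other count was 4546, in a split that kept the diet of 6 of the 8 females and all 6 males. For NZO/HlLtJ females 1 of 35 splits called as many as the real 3 (highest other 0), the smallest share these splits can give. Among these females the second range holds only control and the third only high-fat samples. Without the range term 1 of the 3 genes was called, so chance is not excluded for them. For its males 10 splits are too few for a share under 0.05 (real 2520, highest other 0). In C57BL/6J the real 0 by edgeR was reached in 100 of 100 splits with both sexes (highest other 5), 35 of 35 in females (highest other 1) and 35 of 35 in males (highest other 7). In CAST/EiJ these were 100 of 100 (highest other 209), 35 of 35 (highest other 1) and 35 of 35 (highest other 0), but any split reaches a count of 0, so these splits say nothing about chance. The real splits had 1340, 1021 and 1351 genes at an unadjusted p under 0.05 in C57BL/6J and 1275, 1621 and 408 in CAST/EiJ (93, 37, 144, 57, 144 and 22 by DESeq2). The split of CAST/EiJ with 209 genes may point to a structure of its samples, though the second highest had 1 and what it separates was not tested. Numbers of called lists, at the preset correlation of camera, were also reached in other splits: as many as the real 10 in C57BL/6J in 71 of 100 splits (highest other 18), as many as the real 7 in CAST/EiJ in 87 of 100 (highest other 18) and as many as the real 16 in NZO/HlLtJ in 24 of 100 (highest other 20), so chance cannot be excluded for these.

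The comparisons of the diet effect between groups were listed because the difference itself passed the test. Between the sexes of NZO/HlLtJ 2 genes differed, Slc5a7 by 6.35 and Cplx1 by 5.43 on the log2 scale, male minus female, and without the range term neither was called, at 1.84 ± 1.03 and 1.52 ± 0.93 (SE). The count was 58 without high-fat female 1, 17 without control male 3, 14 without high-fat male 3, 1 without control female 3 or high-fat female 3, and 0 without control female 1 or 4, high-fat female 2 or 4, control male 1 or 2, or high-fat male 1 or 2. NZO/HlLtJ against C57BL/6J differed at 4128 genes. Positive differences were those of Emilin2 (2.64), Scarf2 (1.46), C1qc (1.92), Adgre1 (2.06), C1qb (1.85), Fcgr3 (1.94) and Cd68 (1.84), and negative ones those of Cib3 (-3.39), Eno2 (-0.76), Gad1 (-1.84), Tmem25 (-1.15) and Trpm5 (-1.29). NZO/HlLtJ against CAST/EiJ differed at 5363 genes, with Pfkfb3 at 1.64, C1qc at 1.97, Tlr13 at 2.24, C1qb at 1.93, Csf1r at 2.04, Cd68 at 2.09, C1qa at 1.56 and Tyrobp at 2.05, and with St8sia1 at -1.77, Cib3 at -3.23, Jph3 at -1.51 and Mreg at -2.21. CAST/EiJ against C57BL/6J differed at 3 genes, among them 2210418O10Rik at 4.15 and 9930111J21Rik2 at 5.74. That count was 21 without CAST/EiJ high-fat female 3, 1 without its control female 1, 2, 3 or 4 or high-fat male 1, and 0 without its control male 1, 2 or 3.

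For the sex by diet interaction of NZO/HlLtJ 8 of 100 splits called at least the real 2 genes. The highest other, 4706, came from a split that exchanged the diets of all 6 males and kept those of 6 of the 8 females, which turns the diet response common to both sexes into a difference between them, so these splits do not settle whether chance can be excluded for the 2 genes. In C57BL/6J and CAST/EiJ 100 of 100 splits reached the real 0 by edgeR (highest other 2 each; 1100 and 759 genes at an unadjusted p under 0.05, and 101 and 31 by DESeq2), as any split must, so they say nothing about chance. Between strains, only the real 1 of 40 splits reached 4128 for NZO/HlLtJ against C57BL/6J (highest other 3300). Against CAST/EiJ only the real 1 of 40 reached 5363 (highest other 2339). This is the smallest share 40 splits can give, so chance alone is unlikely for both. For CAST/EiJ against C57BL/6J 4 of 40 splits called at least the real 3 (highest other 47, which may point to a structure of the samples that was not tested), so chance cannot be excluded. Called lists reached the real 14 for NZO/HlLtJ against C57BL/6J in 13 of 40 splits (highest other 17), the real 10 for CAST/EiJ against C57BL/6J in 21 of 40 (highest other 15) and the real 12 for NZO/HlLtJ against CAST/EiJ in 24 of 40 (highest other 18), so chance cannot be excluded for these numbers of lists.

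Some libraries stood far from the other 3 of their group. Chance finds about 1 such library in 20 tests if values are normal and tests independent, which was not checked. Of 99 tests, over 11 measures in each group of 4, 9 found such a library. In the acinar share these were C57BL/6J high-fat male 1 at 14.9% (the others 2.68% to 3.43%), CAST/EiJ control female 4 at 40.6% (1.46% to 7.32%) and NZO/HlLtJ control female 2 at 8.73% (1.91% to 2.69%). In C57BL/6J control male 1 Ins2 made up 7.64% of counts against 6.82% to 6.84%. Aldh1a3 stood at 24.1 CPM in CAST/EiJ high-fat male 4 (15.8 to 16.9) and at 24.4 CPM in NZO/HlLtJ control female 3 (55.8 to 60.6). Mki67 stood at 14.5 CPM in CAST/EiJ control female 1 (10.44 to 11.04) and at 60.7 CPM in NZO/HlLtJ high-fat female 2 (30.2 to 33.8). Lum stood at 9.37 CPM in C57BL/6J high-fat male 1 against 2.32 to 2.94. Groups of 3, among them both male groups of NZO/HlLtJ, were not tested in this way. In NZO/HlLtJ high-fat male 3 Ins2 made up 2.665% of counts, against 5.276% in high-fat male 1 and 5.207% in high-fat male 2.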

How the results depend on the processing

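The fits without the 4 libraries over 15% acinar, within a number range alone, and with all 45 samples and the acinar score were chosen after seeing the data. Diet counts with both sexes are named by strain alone, and unless a next clause says otherwise the cause of a difference was not tested. DESeq2 called 93 genes for diet in C57BL/6J, 37 in its females and 144 in its males, where edgeR called 0 each. In CAST/EiJ it called 57, 144 in females and 22 in males, again against 0, and in NZO/HlLtJ females and males 786 and 3954. For the sex by diet interaction it called 101 in C57BL/6J, 31 in CAST/EiJ and 504 in NZO/HlLtJ, for CAST/EiJ against C57BL/6J 22, and for sex 338, 226 and 197 in C57BL/6J, CAST/EiJ and NZO/HlLtJ. Without the low-count filter NZO/HlLtJ females had 29 genes. Without the range term NZO/HlLtJ females had 1314, its males 4759, its sex by diet interaction 52 and its sex difference 48, and 4 lists passed for diet in CAST/EiJ. With all 45 samples in 1 fit the diet counts were 9 in C57BL/6J, 1 in its males, 9 in CAST/EiJ, 46 in its females, 2970 in NZO/HlLtJ females and 6866 in its males. The sex by diet counts were then 2 in CAST/EiJ and 2852 in NZO/HlLtJ, and the sex counts 19 in CAST/EiJ and 706 in NZO/HlLtJ. With the acinar score as a covariate the diet count by edgeR was 0 in NZO/HlLtJ, 0 in its males and 5 in its females (3115, 2081 and 2660 at an unadjusted p under 0.05), and the sex counts were 29 in C57BL/6J and 5 in CAST/EiJ. In that fit Reg3g and Reg1 turned to -0.025 and -0.66 for diet in NZO/HlLtJ. With the acinar score in the fit of all 45 samples NZO/HlLtJ females had 2857 and males 5937. Without the 4 libraries over 15% acinar the NZO/HlLtJ sex by diet count was 14 and the C57BL/6J sex count 7, with fewer samples in each fit. The first number range alone gave 0 genes by edgeR for diet in NZO/HlLtJ (4708 at an unadjusted p under 0.05), where it holds fewer samples, and the second alone 1 in C57BL/6J. With an estimated correlation in camera, 0 lists passed for diet in C57BL/6J, CAST/EiJ and NZO/HlLtJ and 0 for CAST/EiJ against C57BL/6J, and 2 passed for NZO/HlLtJ against C57BL/6J and 2 against CAST/EiJ. Leaving out 1 library at a time gave counts from 0 to 3 for diet in C57BL/6J, 0 to 0 in its females and 0 to 2 in its males. The ranges were 0 to 7, 0 to 12 and 0 to 0 in CAST/EiJ and its females and males, and 3329 to 6882, 0 to 55 and 0 to 3837 in NZO/HlLtJ and its females and males. For the sex by diet interaction they were 0 to 1, 0 to 7 and 0 to 58 in C57BL/6J, CAST/EiJ and NZO/HlLtJ. Between strains the diet interaction ran from 2949 to 5680 for NZO/HlLtJ against C57BL/6J, 0 to 21 for CAST/EiJ against C57BL/6J and 4290 to 6632 for NZO/HlLtJ against CAST/EiJ, and the control-diet difference from C57BL/6J from 7295 to 9826 for NZO/HlLtJ and 9267 to 9724 for CAST/EiJ. Sex counts ran from 7 to 181, 5 to 14 and 1 to 5 in C57BL/6J, CAST/EiJ and NZO/HlLtJ. Lists for diet ran from 2 to 14, 4 to 11 and 13 to 18 in these strains. For the interactions they ran from 12 to 16 for NZO/HlLtJ against C57BL/6J, 6 to 14 for CAST/EiJ against C57BL/6J and 12 to 15 for NZO/HlLtJ against CAST/EiJ. Counts within 1.5 times the reported one included that for diet in NZO/HlLtJ, at 5821 with relative log expression factors, 6709 by DESeq2, 5947 without the range term, 7464 with all 45 samples, 6496 with the acinar score added and 5244 without the 4 libraries. With the acinar score the interactions of NZO/HlLtJ stood at 2993 against C57BL/6J and 4572 against CAST/EiJ. Of the values of single genes selected by the naming rules, 185 kept their direction and their side of the threshold with relative log expression factors and 2 lost their call. By DESeq2 163 did so and 24 passed newly. Without the range term 169 did so, 10 lost their call and 8 passed newly, and with the acinar covariate 121 did so, 63 lost their call and 1 passed newly. In the first range alone 6 did so and 61 lost their call, and in each of the other ranges alone 18 did so. Without the 4 libraries 176 did so, 9 lost their call and 2 passed newly, and over all fits without 1 library 2792 did so, 114 lost their call and 14 passed newly. Fits within the first number range for C57BL/6J and CAST/EiJ and within the second and the third for NZO/HlLtJ were not run, since these samples lack a group or leave no residual degrees of freedom. No paired analysis was possible because the labels give no replicate numbers. Totals were at least 57203765 counts, and averaged over genes replicates differed by more than counting error. Genes near the filter's minimum count of 10 are measured less exactly, and whether depth or the number of samples limits the diet tests within 1 sex was not tested.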

Other observations

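Of the tests in this part, those of gene families and of strain differences of at least 32-fold were chosen only after the result was seen. Gene families named by the stem of their symbols, most of whose members stand outside the fixed lists, also moved in NZO/HlLtJ islets on the high-fat diet. Of 25 genes of the H2- stem, which includes the proteins that present antigen to T cells, 23 rose and 1 fell (median log2 fold change 1.5). Examples chosen after their values were seen were H2-Aa at 1.89 ± 0.31 (SE, 14 samples) and H2-Ab1 at 1.94 ± 0.32. Toll-like receptor genes, sensors of microbial molecules, rose in 10 of 12 cases (median 1.64), with Tlr7 at 2.32 ± 0.31, while Tlr2 stood at 0.08 ± 0.07. C-type lectins rose in 15 of 21 cases (1.69), with Clec7a at 1.95 ± 0.27, and chemokines of the Ccl stem in 10 of 17 (1.61), with Ccl8 at 3.29 ± 0.79. Collagens rose in 30 of 42 cases and fell in 2 (1.08), with Col1a1 at 1.81 ± 0.32 and Col3a1 at 1.43 ± 0.24, and 4 of the 42 also stand in the fixed lists. Matrix metalloproteinases rose in 14 of 16 cases and fell in 1 (1.45), with Mmp14 at 1.56 ± 0.23, and 1 of them stands in the fixed lists.

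Other families had smaller shifts, and the examples here were chosen after their values were seen. Of 354 Zfp genes, which encode zinc finger proteins, 132 fell and 9 rose (median -0.23), and 1 stands in the fixed lists. Vps genes of endosomal sorting fell in 17 of 32 cases and rose in 0 (-0.21), with Vps35 at -0.54 ± 0.09. Ribosomal protein genes rose in 29 of 75 cases for Rpl (0.30) and in 29 of 58 for Rps (0.33), where 3 fell. Medians kept their sign with relative log expression factors. Of 190 stems with at least 10 genes, camera called 37 at the preset correlation and 0 with an estimated correlation, where the families named here had adjusted p = 0.526, except Rpl with 0.564 and Rps with 0.555. By fry, each of these families moved on balance in 1 direction, with adjusted p from 0.00218 to 0.0129. Fry does not compare a family with the other genes, and 43.8% of all genes had an unadjusted p under 0.05 in this contrast. Families with few called genes passed fry too, such as Srsf (1 of 11 called, adjusted p = 0.00798) and Med (4 of 31, 0.00323). It therefore does not set the families named here apart. These families moved in the same samples as the acinar and macrophage lists.

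The largest differences between strains on the control diet, calls of at least 32-fold, numbered 375 in CAST/EiJ (159 higher, 216 lower) and 131 in NZO/HlLtJ (68 higher, 63 lower). Among those with a transcript sequence, 158 of 374 in CAST/EiJ (42.2%) had most of their sequence in another gene, against 651 of 9432 other calls (6.9%; Fisher's exact p = 7.5e-76, genes not being independent), and 39.7% against 6.3% in NZO/HlLtJ (p = 2e-27). Reads shared with near-identical copies, assigned to 1 copy in a strain and to another elsewhere, are therefore a candidate explanation for part of these calls. Loss of reads with strain variants against a C57BL/6J reference would lower such genes, and 57.6% of the CAST/EiJ calls were lower, 48.1% in NZO/HlLtJ, which leaves it open because losses and gains in the genomes themselves would give both signs. Real differences between the strains, such as genes deleted or duplicated in 1 of them, also stay open and were not tested.

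Of 40 splits of the libraries, only the real 1 reached 8729 genes for NZO/HlLtJ against C57BL/6J (highest other 3474). For CAST/EiJ only the real 1 of 40 reached 9841 (highest other 2195). This is the smallest share 40 splits can give, so chance alone is unlikely for both counts. For sex on the control diet, 1 of 35 splits gave as many as the real 11 in CAST/EiJ (highest other 2) and 1 of 35 as many as the real 5 in NZO/HlLtJ (highest other 1). Both counts include X-linked and Y-linked genes, which a split that mixes the sexes must lose. These splits therefore say nothing about chance for the autosomal genes. In C57BL/6J 2 of 35 splits gave as many as the real 16, the other with 210 genes, so chance cannot be excluded for that count, and a split with so many calls may point to a structure of the samples, which was not tested. Besides those given above, some lists had a median of another sign than their mean or their camera direction, and none of these further lists passed camera. They were beta cell identity for diet in CAST/EiJ, glycolysis and fatty acid synthesis for NZO/HlLtJ against each other strain, other islet endocrine and integrated stress response for NZO/HlLtJ against C57BL/6J, cholesterol synthesis, glycolysis, acinar and duct for CAST/EiJ against C57BL/6J, and the Reg family for NZO/HlLtJ against CAST/EiJ.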
